A study of Mus musculus with 2 samples.

How the data were processed

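Tc17-polarised CD8 T cells of wild-type mice and of mice carrying floxed Nfatc1 with Cd4-Cre were tagged with multiplexing oligonucleotides and sequenced with the 10x Genomics single-cell 3′ kit version 3.1, per the labels' protocols. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, 1 matrix per library, written by Cell Ranger 7.0.0 per the file headers and aligned to the mm10 build per the submitters' processing notes. Whether intronic reads were counted, and the gene annotation used, are not given in the sources used here. The deposited matrices hold 1149 barcodes for the library labelled wild type and 754 for the library labelled Nfatc1-deficient. They also count 12 multiplexing tags, which took 3.83% and 4.20% of all counts and were kept out of the totals.

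Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. That left 1018 (88.6%) and 709 (94.0%); 128 and 41 barcodes exceeded the mitochondrial limit. The median mitochondrial percentage of kept cells was 3.17% in the wild-type-labelled and 2.69% in the deficient-labelled library. UMIs were summed per library over all kept cells and divided by the library total to give CPM, which put both libraries on the same total; 1 UMI corresponds to 0.0409 and 0.0559 CPM, and a count of 0 allows up to 0.123 and 0.168 CPM (3 counts). Intervals are 95%: exact Poisson for a sum, exact binomial (Clopper-Pearson) for a share, and the conditional binomial for a ratio of sums. They cover counting error only. Those of sums and ratios treat UMIs as independent, so they leave out the spread between cells too. Log2 ratios were taken on CPM with a pseudocount of 1, which understates the ratios of low genes, whereas folds in the text are ratios of CPM without it.

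With 1 library per group no test was run, since cells are not replicates. Genes were described by a rule of size fixed before the data were examined: at least 20 CPM in 1 library and at least 2-fold apart on log2 of CPM with the pseudocount. The genes named are Nfatc1, the 15 largest ratios in each direction (leaving out mitochondrial, ribosomal protein, unnamed and receptor segment genes), a fixed set of 12 type 17 and effector genes, 1 of which is not reported here, and the 2 highest and 2 lowest members per list above 20 CPM. A few other genes are named as measurements of cell identity. The 29 gene lists were fixed beforehand too; members averaging at least 1 CPM count as measured, and the median of a list with at least 3 such members was set against 10000 random lists of the same size, each gene drawn from the 50 nearest in mean expression. The percentile describes these 2 libraries. The random lists were drawn for the main values only and were not redrawn where an alternative is set against them. Gene coordinates come from GENCODE M21 (mm10), in which 99.6% of the gene identifiers were found.

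To compare shares of cells across depths, each cell was thinned without replacement to 5000 UMIs. Phases were called from S and G2/M scores over the same thinned cells. Cells were clustered jointly without integration, on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden method at resolution 0.6 (igraph 0.11.9). Scrublet, run in scanpy 1.11.5 with an expected rate of 5%, called 6 and 5 doublets (0.589% and 0.705% of cells), which were kept in the main values and left out in an alternative. Alternatives were edgeR TMM scaling (edgeR 4.0.16, R 4.3.3), median ratio size factors, other totals, pseudocounts, floors, barcode filters, G1 cells only, thinned cells, other thinning depths and UMI cutoffs, and other cluster resolutions. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

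The scripts were tested on simulated counts drawn with Poisson noise from the real gene means and library sizes for the comparison of the 2 libraries. The size rule recovered all 50 genes changed 2.5-fold, all 50 changed 3-fold and all 50 changed 4-fold, 0 of 50 changed 1.5-fold, and 0 of 5151 unchanged genes. Ratio intervals held the true value for 94.8% of 1000 genes, and 6% of 100 lists of unchanged genes fell outside the central 95% of random lists. The simulation holds no spread between mice or cultures, so it does not test for that.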

Results

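Single-cell RNA sequencing was carried out on mouse CD8 T cells that had been isolated from mesenteric lymph nodes, cultured under conditions that direct T cells toward interleukin-17 production (Tc17 cells), and restimulated for 3 h with PMA (100 ng/ml) and ionomycin (10 μg/ml). PMA and ionomycin together mimic T-cell receptor signalling, and the calcium signal set off by ionomycin activates NFAT transcription factors. The 2 libraries were 1 of cells from wild-type mice and 1 of cells from mice in which floxed Nfatc1 was to be deleted in T cells by Cd4-Cre. With 1 library per group, no difference had a replicate check, no p-value was computed, and every interval covers counting error only, not the spread between mice or cultures. Intervals of CPM and of folds also leave out the spread between cells, which matters most for genes carried by few cells. The library labelled wild type held 1018 cells after filtering, with a median of 20906 UMIs and 3936 genes per cell and 24452538 UMIs in all. The library labelled Nfatc1-deficient held 709 cells, with medians of 21436 UMIs and 3990 genes and 17898193 UMIs. Because the level of Nfatc1 itself ran against the genotype label, the libraries are called wild-type-labelled and deficient-labelled throughout, and every direction below rests on those labels.

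Nfatc1 transcripts were more abundant in the deficient-labelled library, the opposite of what the genotype names. Nfatc1 (ENSMUSG00000033016, chromosome 18, 80606205 to 80713071, mm10) stood at 136 CPM (2436 UMIs) against 39.8 CPM (974 UMIs) in the wild-type-labelled library, a 3.42-fold difference (95% counting interval 3.17 to 3.68). At a fixed depth of 5000 UMIs per cell, 46.3% of deficient-labelled cells (42.5 to 50.1) and 18.7% of wild-type-labelled cells (16.4 to 21.3) had an Nfatc1 UMI. The kit reads transcripts near their 3′ end, and which exons were deleted is not given in the sources used here, so tags outside the deleted part neither check the deletion nor exclude it. Among 19 genes of the NFAT and calcineurin pathway, Orai1, the pore of the store-operated calcium channel, was 2.70-fold higher in the deficient-labelled library (2.57 to 2.83). Nfatc2, encoding a related NFAT factor, was 3.81-fold lower there (3.12 to 4.69), at 6.48 against 24.7 CPM. The other 17 members lay within 2-fold, among them Itpr1 (88.8 against 54.3 CPM) and Stim1 (31.5 against 44.3 CPM), and the list median of 0.18 on the log2 scale sat at percentile 97.9 of 10000 random lists matched on expression. It lay inside their central 95% under 3 alternatives, such as 0.14 at a pseudocount of 5 CPM.

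The interleukin-17 genes were compared first, since the cells had been cultured toward interleukin-17 production. Il17a (chromosome 1, 20730905 to 20734496) was 3.11-fold lower in the deficient-labelled library (3.08 to 3.13), at 3572 CPM against 11093 CPM, a log2 ratio of -1.63. Il17f, its neighbour on chromosome 1 (20777146 to 20790617), was 2.10-fold lower (2.08 to 2.12), at 3935 against 8253 CPM. Of 23 measured genes of the type 17 list, 7 were at least 2-fold lower and 2 at least 2-fold higher, with 14 within 2-fold. The lower ones included Ccr6, the chemokine receptor of type 17 cells, at 16.2 against 52.5 CPM, and Il21, at 15.9 against 36.6 CPM. The 2 higher ones were Ccl20, the ligand of that receptor (45.3 against 13.8 CPM), and Il23r (11.6 against 4.58 CPM). Ahr stood at 120 against 68.9 CPM. The list median was -0.25 on the log2 scale, at percentile 0.21 of the matched random lists. As a mean of per-cell CPM it was -0.060, inside their central 95%. It was 0.17 when a cytotoxic-like cluster of cells was left out, an alternative chosen after the data were seen, under which Il17a was still lower with a log2 ratio of -1.19.

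Counted per cell, strong Il17a expression was found in a smaller share of deficient-labelled cells. After each cell was thinned to 5000 UMIs, which left out 14 wild-type-labelled and 11 deficient-labelled cells, at least 5 Il17a UMIs were present in 62.5% of 1004 wild-type-labelled cells (exact binomial 95% interval 59.5 to 65.6) and in 24.1% of 698 deficient-labelled cells (20.9 to 27.4). The median cell held 31 Il17a UMIs in the former and 1 in the latter. A minimum of 1 UMI gave 79.0% and 54.6%, and 93.8% and 88.0% without thinning. A cutoff of 1 UMI does not separate low expression from free RNA. In the cluster with the least Il17a, picked for that reason, 62.0% of 50 wild-type-labelled cells had 1 or more Il17a UMIs and 0 had 5 or more (an upper limit of 7.11%), at a median of 10843 UMIs before thinning. Il17f followed the same order, with at least 5 UMIs in 73.4% and 39.1% of cells, and both genes together reached that level in 57.1% and 20.1%. Il22 and Csf2 were carried by few cells: Il22 was 2.14-fold lower in the deficient-labelled library (7.32 against 15.7 CPM), and an Il22 UMI was found in 0.498% and 0.716% of wild-type-labelled and deficient-labelled cells. Csf2, at 26.5 against 75.5 CPM, was found in 3.30% of deficient-labelled and 5.18% of wild-type-labelled cells.

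**Figure D1:**
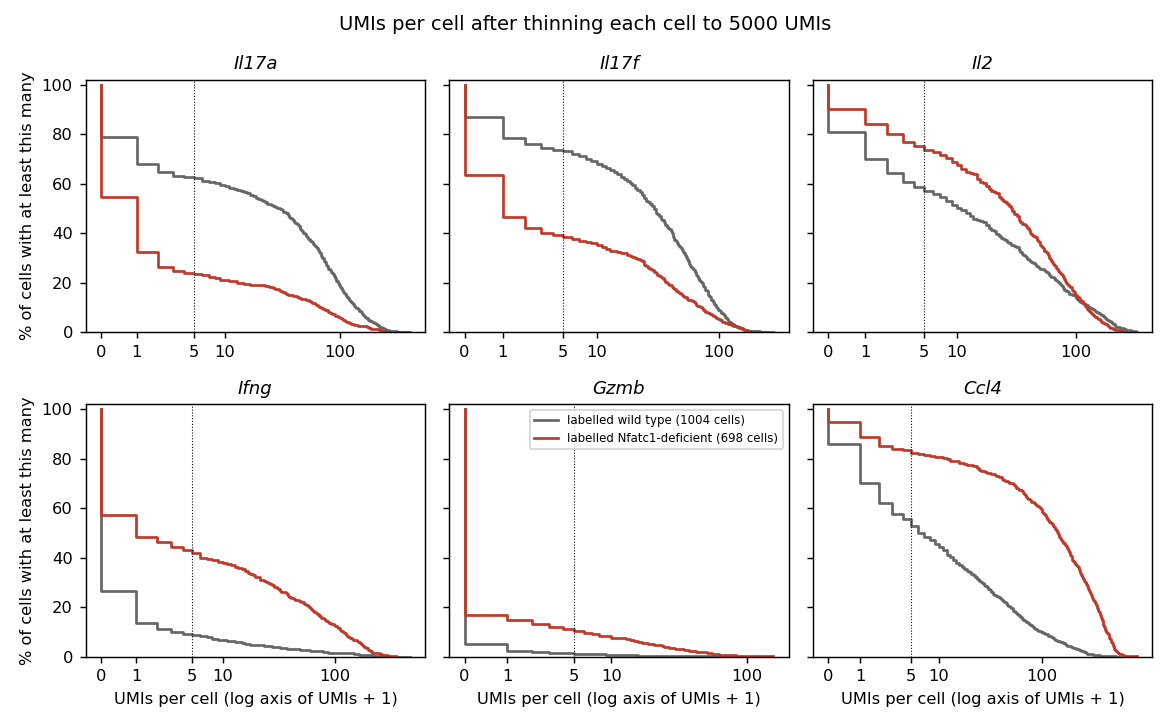
Percentage of cells (vertical axis) with at least a given number of UMIs of each gene (horizontal axis, log scale of UMIs + 1) after thinning to 5000 UMIs, for 1004 cells of the library labelled wild type (grey) and 698 of the library labelled Nfatc1-deficient (red). At the dotted line of 5 UMIs the red curve lies below the grey one for Il17a (24.1% against 62.5%) and Il17f, and above it for Ifng (43.0% against 9.16%), Gzmb, Il2 and Ccl4.

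Effector cytokines and chemokines of another kind were more abundant in the deficient-labelled library. Ifng, encoding interferon-γ, was 5.59-fold higher (5.52 to 5.65), at 7368 against 1319 CPM, and Gzmb, encoding the cytotoxic protease granzyme B, was 6.24-fold higher, at 746 against 120 CPM. The chemokine genes Ccl3 and Ccl4, adjacent on chromosome 11 (83647844 to 83649355 and 83662584 to 83664683), stood at 7429 against 825 CPM and at 35809 against 6435 CPM, and Xcl1 was 4.82-fold higher. Ccl4 alone took 3.58% of all UMIs in that library against 0.644%, and Xcl1 took 2.91% against 0.603%. Of 26 measured cytokine and chemokine genes, 13 were at least 2-fold higher and 5 at least 2-fold lower, the list took 9.23% of UMIs against 2.38%, and its median of 1.05 on the log2 scale was at percentile 100 of the random lists. Among members of at least 20 CPM in 1 library, the widest ratios with the pseudocount were those of Ccl9, Ccl1 and, in the other direction, Il9. Ccl9 stood at 35.7 against 0.409 CPM (87.3-fold, 47.2 to 183), Ccl1 at 583 against 63.1 CPM, and Il9 at 2.57 against 73.1 CPM (28.4-fold lower, 21.2 to 39.0). Few cells carried Il9: before thinning, a UMI was found in 3.93% of wild-type-labelled and 2.40% of deficient-labelled cells. In the same order the shares were 0.589% and 4.09% for Ccl9, and 5.70% and 15.4% for Ccl1. The 85 wild-type-labelled cells of a cycling-like cluster held 69.1% of that library's Il9 UMIs. Il2 was 1.30-fold higher and Tnf 1.80-fold higher.

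Members of the cytotoxic list went in both directions. Of its 28 measured members, 5 were at least 2-fold higher and 2 at least 2-fold lower in the deficient-labelled library, with a median of 0.04 at percentile 79.8; among cells called G1 the median was 0.26, above the central 95% of the random lists. Tbx21, encoding the T-bet transcription factor that drives Ifng in type 1 cells, was 2.45-fold lower (2.12 to 2.84), and Klrk1 was at 12.1 against 22.7 CPM. At least 5 Ifng UMIs per 5000 were present in 43.0% of deficient-labelled cells (39.3 to 46.7) and 9.16% of wild-type-labelled cells (7.45 to 11.1), and at least 5 Gzmb UMIs in 77 of 698 cells (8.80 to 13.6%) and 14 of 1004 cells (0.764 to 2.33%). For Ccl3 the shares were 58.3% and 16.3%, and for Xcl1 81.1% and 35.6%. Cells with at least 5 UMIs of both Il17a and Ifng made up 4.73% (3.28 to 6.58) and 4.28% (3.12 to 5.73), with overlapping intervals. With at least 1 UMI of both, the shares were 26.2% (23.0 to 29.6) and 19.1% (16.7 to 21.7). The Ifng and Gzmb log2 ratios of 2.48 and 2.63 became 0.81 and 0.65 without the cytotoxic-like cluster, which those genes themselves define, and 3.14 and 4.41 among cells called G1. Among G1 cells the Il9 log2 ratio was -2.81 instead of -4.38.

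Across the transcriptome, 5584 genes reached 20 CPM in at least 1 library; 127 of these were at least 2-fold higher and 116 at least 2-fold lower in the deficient-labelled library, together 4.35%. The median log2 ratio was 0.03, with an SD of 0.46 across genes. These counts describe the 2 libraries and moved with the expression floor, to 249 and 370 genes with none and to 87 and 68 at 50 CPM. The 15 genes with the largest ratios upward were Ccl9, Ccl1, Ccl3, Penk, Tex15, Jaml, Eif3j2, Gzmb, Mpzl2, Ifng, Ccl4, Morrbid, Cd160, Map3k8 and Xcl1. Penk, encoding the enkephalin precursor, stood at 159 against 17.2 CPM, Jaml, an adhesion receptor, at 155 against 22.2 CPM, and Cd160, a receptor of activated cytotoxic lymphocytes, at 597 against 118 CPM. Before thinning, a Penk UMI was found in only 12.1% of deficient-labelled and 4.03% of wild-type-labelled cells, against 61.6% and 20.9% for Jaml. Eif3j2 (70.1 against 9.94 CPM) is a near-identical copy of Eif3j1, so its assignment is uncertain. The 15 largest ratios downward belonged to Il9, Pdpn, Mmp10, Upp1, Ntrk3, Ermn, Enc1, Scd2, Batf3, AA467197, Ifi211, Vegfa, Alpk2, Tnfrsf25 and Acsl3. Among them, Pdpn, encoding podoplanin, was 16.2-fold lower (11.9 to 22.6), Mmp10, a matrix metalloproteinase, at 14.9 against 176 CPM, Upp1, encoding uridine phosphorylase, at 9.95 against 119 CPM, and Batf3, an AP-1 family factor, at 13.6 against 78.1 CPM. Tnfrsf25, encoding a TNF receptor family member, was at 10.1 against 45.0 CPM. The Ccl9 ratio rested on 10 UMIs in the wild-type-labelled library and on the pseudocount, its log2 value of 4.70 running from 2.91 at 5 CPM to 6.14 at 0.1 CPM.

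**Figure D2:**
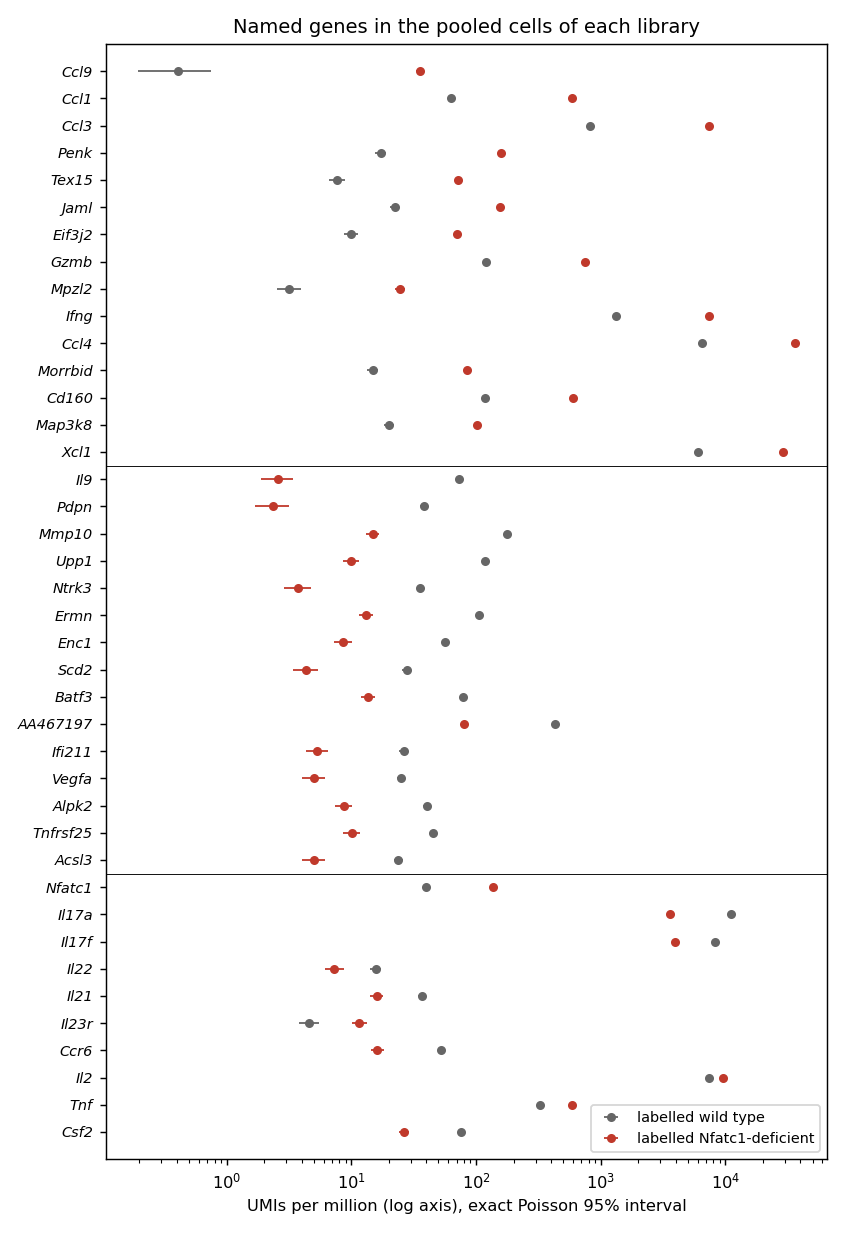
Level of each gene in CPM (log axis) in the pooled cells of the library labelled wild type (grey, 1018 cells) and the library labelled Nfatc1-deficient (red, 709 cells), with exact Poisson 95% intervals for counting error. The upper block holds the 15 largest ratios upward, the middle block the 15 largest downward, and the lower block genes named in advance, in which Nfatc1 is higher (136 against 39.8) and Il17a lower (3572 against 11093) in the library labelled Nfatc1-deficient.

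Genes of sterol and lipid synthesis were lower together in the deficient-labelled library. Of 22 measured members of the cholesterol and lipid list, 21 were lower, 13 of them at least 2-fold, and the median log2 ratio was -1.21, at percentile 0 of the random lists. Msmo1, encoding sterol-C4-methyl oxidase, was 4.19-fold lower (3.79 to 4.63), at 25.4 against 106 CPM, and the fatty acid desaturase gene Scd2 was 6.45-fold lower (5.09 to 8.27). The exception was Stard4 (27.3 against 25.4 CPM), and Idi1 was close to level (136 against 143 CPM). All 18 measured genes of amino acid supply and the integrated stress response were lower, 5 at least 2-fold, with a median of -0.62 at percentile 0. Trib3 was 3.55-fold lower (2.94 to 4.30) and Chac1 2.48-fold lower (2.11 to 2.93), both targets of the ATF4 stress pathway, whereas the transporter gene Slc3a2 was level (273 against 274 CPM). The glycolysis and hypoxia list had 27 measured members, 0 at least 2-fold higher and 3 at least 2-fold lower, and a median of -0.26 at percentile 0.03. In it, Vegfa was 4.97-fold lower (3.98 to 6.27) and Egln3 2.69-fold lower, with, in the other direction, Hilpda at 97.6 against 50.3 CPM. Oxidative phosphorylation genes all lay within 2-fold, 24 of 30 lower, with a median of -0.14 at percentile 0.15. Without the cytotoxic-like cluster it was -0.058, inside the random range drawn for the main values. That removal also moved the median of all genes reaching 20 CPM by 0.070. The value of -0.058 therefore does not show that these genes rose relative to the rest. Ribosomal protein genes took 22.4% of UMIs in the deficient-labelled and 27.8% in the wild-type-labelled library.

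**Figure D3:**
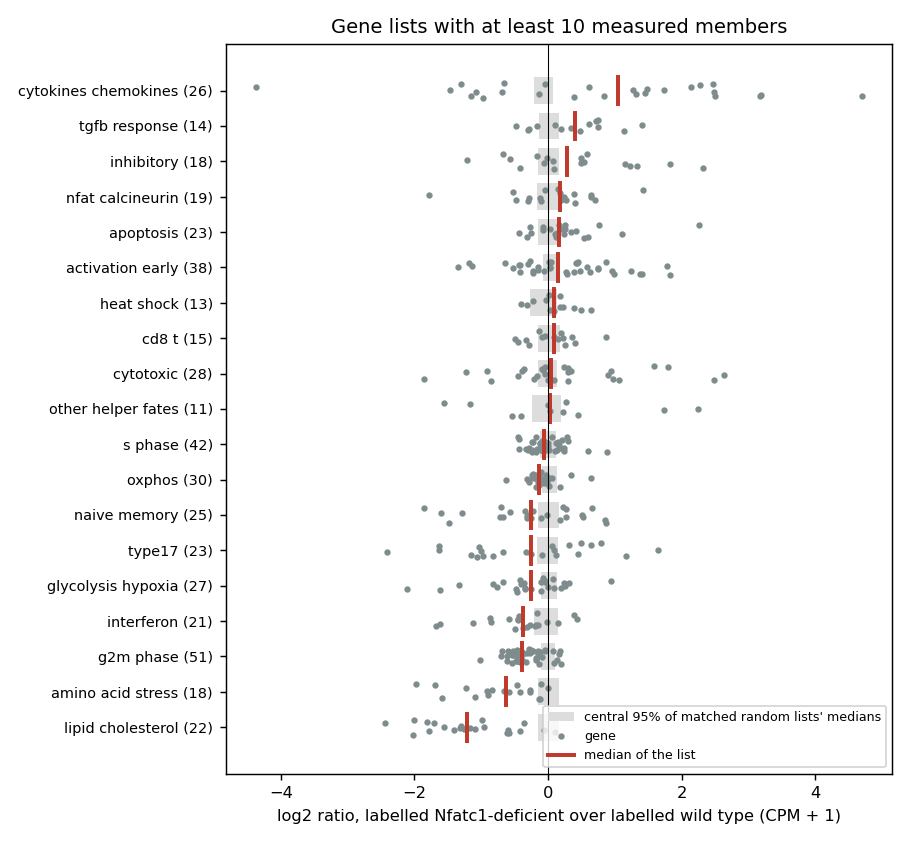
Log2 ratio of each gene (points, CPM + 1, library labelled Nfatc1-deficient over library labelled wild type) in the lists with at least 10 measured members, whose number stands in brackets; red bars are list medians and grey boxes the central 95% of medians of 10000 matched random lists. The cytokine and chemokine median (1.05) lies to the right of its box and the lipid and cholesterol median (-1.21) to the left.

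Genes linked to activation and inhibition of T cells showed mixed directions. Of 18 inhibitory receptors and exhaustion-linked factors, 5 were at least 2-fold higher and 1 at least 2-fold lower in the deficient-labelled library, with a median of 0.28 at percentile 99.95. Havcr2, encoding TIM-3, was 3.67-fold higher (3.31 to 4.08), while Cd200 was at 67.3 against 108 CPM and Socs1 at 54.5 against 73.0 CPM. Among 38 early activation genes, 5 were at least 2-fold higher and 3 at least 2-fold lower (median 0.15, percentile 99.6). The orphan receptor gene Nr4a3 (231 against 66.6 CPM) and the feedback inhibitor gene Spry1 (137 against 37.7 CPM) were at the upper end, and the costimulator gene Icos (75.9 against 194 CPM) and the phosphatase gene Dusp5 (81.1 against 185 CPM) at the lower. The TGF-β list had 14 members with a median of 0.41 at percentile 100, including the integrin gene Itgav (508 against 231 CPM) and Tgfbr1 (111 against 65.5 CPM), with Tgfbr2 at 42.2 against 59.3 CPM and Skil at 48.7 against 60.0 CPM. Of 25 naive and memory genes, 4 were at least 2-fold lower and 0 at least 2-fold higher (median -0.25, percentile 0.11), Id3 standing at 43.4 against 134 CPM and Cd27 at 196 against 107 CPM. That median was 0.03 without the cytotoxic-like cluster. The 21 interferon-response genes had a median of -0.37 (percentile 0.04), with Ly6a 3.21-fold lower (3.06 to 3.38) and Slfn1 3.32-fold lower (2.78 to 3.99); the median was -0.034 among cells called G1, inside the central 95% of the random lists. With members averaging at least 5 CPM, the inhibitory and early activation medians of 0.068 and 0.043 lay inside theirs too. Among 23 apoptosis genes (median 0.17, percentile 99.1, but 0.13 and inside the random range as a mean of per-cell CPM), Bcl2l11, encoding the death-promoting protein BIM, was 5.30-fold higher (4.51 to 6.26) and Trp53inp1 2.18-fold higher. Of 11 genes of other helper fates, Gata3 was 3.52-fold higher (3.08 to 4.04), and the list median was 0.04 (percentile 63.8). Heat shock genes all lay within 2-fold (13 genes, median 0.09, percentile 95.7).

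Cell cycle phase shares had overlapping intervals in the 2 libraries at the depth used. At 5000 UMIs per cell, 54.3% of deficient-labelled cells (50.5 to 58.0) and 51.6% of wild-type-labelled cells (48.5 to 54.7) were called G1, 25.8% and 26.5% S, and 19.9% and 21.9% G2/M. The S-phase list had a median log2 ratio of -0.07 (42 genes, percentile 14.3). The G2/M list had a median of -0.40 (51 genes, 45 of them lower in the deficient-labelled library, percentile 0), with 1 gene at least 2-fold lower, the ubiquitin-conjugating enzyme gene Ube2c (50.3 against 103 CPM). Among cells called G1, the G2/M list median was -0.10, but that call was made from the same lists, so a smaller difference there is built in. Without the cytotoxic-like cluster the G2/M median was -0.036 and the S-phase median 0.27. Inside the cycling-like cluster, 41 of 42 S-phase genes were higher in deficient-labelled cells (median 0.46), whereas the G2/M median was -0.066 (20 genes higher, 31 lower). The S-phase median was -0.15 in the naive-like cluster and 0.18 in an unnamed cluster with at least 40 cells of each library. The G2/M medians there were -0.12 and 0.20. The direction for cell cycle genes thus depended on the list and on the cells compared.

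Cells of both libraries carried CD8 T-cell transcripts. At least 3 of 15 CD8 T-cell markers were detected in 99.8% of wild-type-labelled and 99.9% of deficient-labelled cells, Cd8b1 in 96.6% and 96.5%, and Cd4 in 0.295% and 0.564%. Most of the 15, such as Cd3e and Trac, are shared by other T cells, so of these values only the Cd8b1 and Cd4 shares bear on CD8 identity. No cell of 1018 or of 709 held an Ncr1 UMI, a marker of natural killer cells, so detection was below 0.362% and 0.519% of cells; cells with the transcript but no captured UMI are not covered. At least 3 B-cell markers were detected in 6.78% of wild-type-labelled and 2.96% of deficient-labelled cells, at least 3 myeloid markers in 7.17% and 6.35%, and at least 3 dendritic-cell markers in 3.05% and 0.705%, while Lyz2 was detected in 1 cell of each library. Some of these markers were widespread: Cd74 was detected in 28.6% and 19.7% of cells, Cst3 in 76.3% and 69.8%, and Bst2 in 72.8% and 52.2%. Reaching 3 markers therefore does not by itself show a cell of another type. The median log2 ratio of the CD8 T-cell list was 0.09 (percentile 86.9). Joint clustering gave 8 clusters, none led by 3 or more markers of another cell type, so none was left out. A cytotoxic-like, a naive-like and a cycling-like cluster were named from the markers fixed in advance. The other 5 stayed unnamed, since fewer than 3 markers of any state led them. Most clusters came mainly from 1 library, so cluster sizes were not compared, apart from the share of the cytotoxic-like cluster given further below. Xist was at 480 CPM in the deficient-labelled and 534 CPM in the wild-type-labelled library; its antisense partner Tsix (45.7 and 56.8 CPM) overlaps it, so the 2 cannot be fully separated.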

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

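All tests in this part were chosen after the results were seen. Counts of multiplexing tags, which no comparison used, held a signal above the limit of 3 that a count of 0 allows. A different tag led every barcode of each library, and 2 further tags that led none took 4.20% and 2.66% of tag counts in the wild-type-labelled library and 3.58% and 1.93% in the deficient-labelled one. The tag that led the other library took 5.39% and 2.62%, a level of the same order, and whether the 2 further tags are carry-over or come from other samples was not tested.

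The level of Nfatc1 ran against the genotype label. A different mix of cell states is argued against for the 3 clusters that held at least 40 cells of each library: Nfatc1, which was not among the genes the clusters were built on, was higher in the deficient-labelled cells of each, by 1.82-fold at the least (1.35 to 2.45). The first test written weighted clusters as in the wild-type-labelled library and gave 2.56-fold (2.15 to 3.02); it was replaced after its value was seen, because it rests on 16 and 4 deficient-labelled cells in the 2 largest wild-type-labelled clusters. A swap of the 2 library labels stays open, since the 3.42-fold difference as measured is what a swap could give and no further library is there to check it. Transcripts of a deleted allele that are still read at their 3′ end may be the source of the UMIs as well, since the deleted exons are not given in the sources used here. An Nfatc1 UMI was found in 86.0% of deficient-labelled cells before thinning, which shows that the gene was read, but not why its level was higher.

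The lower Il17a level had 2 technical explanations to weigh. Abundant chemokine transcripts taking a larger share of the counts are argued against by their size. The cytokine and chemokine list took 9.23% of UMIs against 2.38%, too small a part of the total to lower another gene 3.11-fold. Scaled to a total without mitochondrial, ribosomal protein and the 10 most abundant genes, the log2 ratio was -1.67. That scaling does not isolate the chemokines, since ribosomal protein genes differed in share too. A different mix of cell states stays open: with the deficient-labelled clusters weighted as in the wild-type-labelled library, the ratio of the former to the latter was 0.694 instead of 0.322, but this rests on the same 16 and 4 cells, and the clusters were built on Il17a among other genes. This explanation was first judged excluded and was reopened for those reasons after the value was seen. Whether such a mix would itself follow from the genotype was not tested. Inside the 3 clusters with at least 40 cells of each library, Il17a was lower in deficient-labelled cells. The folds were 1.80 (cycling-like), 2.65 (naive-like) and 1.39 (unnamed). Those clusters leave out the 2 largest wild-type-labelled ones, so these folds do not settle the question either.

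The higher Ifng and Gzmb levels could come from cells of another type that escaped the CD8 bead isolation. Natural killer or γδ T cells are argued against for the 300 deficient-labelled cells with at least 5 Ifng UMIs. Of these, 98.3% (96.2 to 99.5) had a Cd8a or Cd8b1 UMI, 0 had an Ncr1 or Klrb1c UMI, 0 an Fcer1g or Tyrobp UMI and 1 a Trdc UMI. The Cd8a or Cd8b1 share was 97.0% in deficient-labelled cells with fewer Ifng UMIs, and it required only 1 UMI before thinning. Cells chosen by Gzmb were not examined. The cytotoxic-like cluster held 30.7% of deficient-labelled cells (27.4 to 34.3) and 0.982% of wild-type-labelled cells (0.472 to 1.80). It carried 81.0% of the Ifng and 84.4% of the Gzmb UMIs of the deficient-labelled library. Whether this difference in share accounts for the higher levels stays open. With clusters weighted as in the wild-type-labelled library the Ifng ratio was 0.815, but the Gzmb ratio stayed above 1, at 1.46. Neither ratio settles it: both rest on the same 16 and 4 cells, which held 1 and 0 Gzmb UMIs, and both genes are among those that define the clusters. A difference of genotype is among the open explanations.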

How the results depend on the processing

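The alternatives without the naive-like or the cytotoxic-like cluster were chosen after the data were seen; the others were fixed beforehand. No cluster was left out of the main values, so including all clusters is identical to them. The Il17a log2 ratio of -1.63 stayed negative in all 13 alternatives, from -2.06 in G1 cells to -1.19 without the cytotoxic-like cluster, with -1.67 on the total without mitochondrial, ribosomal protein and top 10 genes, -1.54 as a mean of per-cell CPM and -1.55 in thinned cells. The type 17 median of -0.25 was -0.060, inside the random range, as a mean of per-cell CPM and 0.17 without the cytotoxic-like cluster, under which the naive and memory median was 0.032; the causes were not tested beyond that removal. The 127 higher and 116 lower genes became 249 and 370 without a floor; at 5 CPM 249 were lower and at 50 CPM 68, as more or fewer genes entered. With TMM scaling 127 and 117 genes passed, on the total without mitochondrial, ribosomal protein and top 10 genes 137 and 167, and without the cytotoxic-like cluster 160 and 98, so the balance of directions depended on these choices. The share of cells with an Il17a UMI, 79.0% and 54.6%, was 70.9% and 36.4% at 2000 UMIs, 87.7% and 68.7% at 10000, 93.8% and 88.0% unthinned, 67.8% and 32.2% with at least 2 UMIs and 62.5% and 24.1% with at least 5, always higher in the wild-type-labelled library. G1 shares (wild-type-labelled first) were 47.6% and 44.7% at 2000 UMIs, with 33.1% of deficient-labelled cells in S, and 62.6% and 67.8% unthinned, with 23.7% of wild-type-labelled cells in S and 13.8% and 9.17% in G2/M; the order of the G1 shares thus depended on the depth. Of 1508 values of single named genes other than Il17a under alternatives, 1269 stayed, 239 moved and 0 of those at least 2-fold apart reversed. A value stayed if it lay no further from the main value than the farther end of the counting interval. For single genes that interval was taken without the pseudocount, which widens the allowed distance for low genes such as Ccl9. Of 318 medians of the 23 lists other than type 17, 277 stayed, 40 moved and 1 of those outside the central 95% of random lists reversed. That was the naive and memory median without the cytotoxic-like cluster. The type 17 median, counted apart, reversed under the same removal. Of 16 lists outside the central 95% of the random lists drawn for the main values, 6 stayed outside under every alternative (cytokines and chemokines, TGF-β, glycolysis and hypoxia, cholesterol and lipid, amino acid and stress, dendritic cell), and 10 fell inside under at least 1. Of 8 lists inside it, 6 left it under at least 1 (cytotoxic, S-phase, heat shock, B-cell, natural killer and CD8 T-cell). The range was not redrawn for the alternatives, whereas the median of all genes reaching 20 CPM could shift. It moved by 0.070 without the cytotoxic-like cluster and by -0.039 on the total without mitochondrial, ribosomal protein and top 10 genes. Lists near a limit could cross it for that reason alone. No alternative measures the spread between mice.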

Other observations

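Lists of genes were also compared inside the 3 clusters that held at least 40 cells of each library, a choice made after the data were seen. Amino acid and stress-response genes were lower in deficient-labelled cells in each: the median log2 ratio was -0.84 in the cycling-like cluster (85 wild-type-labelled and 40 deficient-labelled cells), -0.62 in the naive-like cluster (60 and 59 cells) and -1.14 in an unnamed cluster (159 and 43 cells). Cholesterol and lipid genes had medians of -0.74, -0.62 and -0.24 in the same order. Cytokine and chemokine genes had medians of 0.91, 0.74 and -0.11. Xcl1 was 5.92-fold, 6.19-fold and 4.20-fold higher in deficient-labelled cells, and Ccl3 6.74-fold, 6.44-fold and 2.38-fold higher. Ifng did not keep 1 direction: its sum was 35.2-fold higher in deficient-labelled cells of the naive-like cluster (2316 against 65.8 CPM), where 10.5% of 57 thinned cells had at least 5 UMIs and the median was 0, so few cells carry it, and 1.28-fold higher in the cycling-like cluster; it was 2.59-fold lower in the unnamed one (690 against 1784 CPM). Il17a was lower in deficient-labelled cells by 1.80-fold, 2.65-fold and 1.39-fold. These ratios come from 40 to 59 deficient-labelled cells each and were not tested.

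Morrbid, a long noncoding RNA gene on chromosome 2 (128178319 to 128502765), was 5.74-fold higher in the deficient-labelled library (5.12 to 6.45), and so was its neighbour Bcl2l11 (128126038 to 128162547), by 5.30-fold. Ccl9 UMIs were found in 4.09% of deficient-labelled and 0.589% of wild-type-labelled cells before thinning. Il13, chosen after its values were seen, stood at 6.48 against 0.327 CPM and Il10 at 231 against 95.3 CPM, while Il9 was lower in the deficient-labelled library. Marker lists of other cell types mostly had few measured members, and some of these, such as Bst2 of the dendritic-cell list, were detected in many cells of both libraries. The 9 measured B-cell genes had a median log2 ratio of -0.14 (percentile 17.9; -0.65 and outside the random range among cells called G1, and 0.20 as a mean of per-cell CPM), with Ebf1 at 7.32 against 26.1 CPM and Ighm at 26.8 against 16.8 CPM. The medians were -0.09 for 5 myeloid genes (percentile 41.1), -1.13 for 3 dendritic-cell genes (percentile 0), 0.16 for 4 natural killer genes (percentile 84.8; -1.16 in thinned cells) and -0.77 for 3 CD4 T-cell genes (percentile 0.99). Of the neutrophil and mast-cell list only Kit was measured, 2.64-fold lower in the deficient-labelled library, and of the stromal list only Pdpn and Pecam1 (1.64-fold lower). No γδ T-cell, erythroid or platelet gene averaged 1 CPM, and of the sex-linked list only Xist and Tsix did, in both libraries.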
